A study of Mus musculus with 18 samples.

How the data were processed

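The series holds 18 samples of mouse liver tumour: 9 libraries precipitated with a MYC antibody and 9 input libraries, 3 of each per Arid1a genotype. Groups and replicate numbers were taken from the sample titles. The input samples had no separate file used here. Reads were processed by the submitters with Bowtie2 2.2.3, Picard, MACS2 2.0.10.20131216 and HOMER on mm10, per the submitters' processing notes; the threshold of the peak caller is not given in the sources used here. Each MYC library has its own peak list, so peaks were called per library and the library is the replicate. Nothing in the labels says that libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

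The deposited lists are in the format that MACS2 writes, without a header. They give for each peak the authors' fold enrichment over background (a ratio at the summit), the authors' −log10 p and −log10 q, a deposited integer score, and the offset of the summit from the peak start as deposited. Folds are the authors' own values per peak and were used only to describe, rank or filter peaks within a list, except that the fold and the −log10 p of each peak were also solved together for the number of reads at the summit and the local background. This uses the form of the MACS2 values, in which the fold is the ratio of the scaled reads plus 1 to the background plus 1 and p is a Poisson upper tail. For 99.9% of peaks exactly 1 whole number of reads solved both values within an allowance for the rounding of the deposited values, and the other peaks, with more than 1 solution, were left out of what uses these reads. The solution also gave the ratio by which the MYC library was scaled to its input, and, from the lowest background in a list, the input depth per kb. In Homo replicate 1 that lowest background rests on 2 peaks. The shortest peak of each list was taken as the fragment length (170 bp in WT replicate 1, 173 bp in Homo replicate 2, and 183 to 201 bp in the other 7 libraries).

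Gene positions came from a RefSeq table of GRCm38.p6, the assembly behind mm10. It gives gene spans without strand and no sequence was used, so a design written for transcription start sites was replaced by gene ends: a peak counts at a gene when its summit lies within 1 kb of either end of a protein-coding gene span. The planned counts of the MYC motif and of CpG-rich promoters were not run for the same reason. Shares per library carry exact Clopper-Pearson 95% intervals, which cover counting error only.

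Number of peaks (as log10) and gene-end share were compared with two-sided exact permutation tests over libraries: the 3 pairs of genotypes (10 distinct splits, smallest p 0.1), the sum of squares between 3 genotypes, and Homo minus WT over the same assignments, with Benjamini-Hochberg adjustment over these 5 tests. Peak lists were compared by the share of the shorter list that overlaps the longer by at least 1 bp, against 100 random placements, and within-genotype against between-genotype means by exact permutation. Peaks were merged into regions with bedtools 2.31.1, and a region was counted for a genotype with a peak in at least 2 of its 3 libraries. Gene lists were tested with Fisher's exact test against all protein-coding genes on the chromosomes used, and the number of bound members per library by exact permutation over 3 genotypes; lists, tests, and most alternatives were fixed before the data were examined. The lists were ribosome biogenesis, ribosomal proteins, translation factors, nucleotide and polyamine synthesis, glycolysis, mitochondrial biogenesis, cell cycle, MYC network, SWI/SNF subunits, hepatocyte identity, cytochrome P450, fetal liver and hepatoblastoma, EMT and metastasis, circadian E-box genes, immune cells, endothelial and stellate cells and cholangiocytes, and a small list of transgene loci that was described only.

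Genes were named by a rule fixed in advance: the 20 genes with a peak in the most libraries, up to 10 per pair of genotypes and direction, up to 4 members per list with a peak in at least 4 libraries, Arid1a, Myc, Alb and Cebpb, and 5 regions per genotype away from gene ends. These regions were ranked over all 9 libraries, so they are the same for each genotype by construction. A gene that the rule named is not reported here. Alternatives covered stricter limits (−log10 q of at least 5, fold of at least 5), other gene-end windows (250 bp and 5 kb), other overlap rules, each library left out, the replicate number as a block, and, added after the data were seen, WT replicate 1 and Homo replicate 2 left out together, 1 p limit in every library (−log10 p of at least 10), the same limit after thinning to the shallowest input, and gene ends of any biotype. Thinning was done by calculation. The summit reads and local background of each listed peak were multiplied by 1 factor per library, and p was recomputed. That factor was the lowest input depth per kb divided by the library's own. No reads were drawn and no peaks were called anew, so no peak outside the deposited lists could appear. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

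The scripts were tested on simulated data. The 3-genotype permutation test gave p of at most 0.05 in 5.67% of 300 sets without a difference. It did so in 100% of 100 sets with a difference of 2 at an SD of 0.3. That difference is far larger against its spread than those between genotypes found here, so the power for such differences was not measured. Lists made enriched were called in 98.3% of cases and lists left at background in 0.714%, over 21887 genes. Summit read numbers were recovered for 100% of 386 simulated summits.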

Results

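MYC binding was measured by chromatin immunoprecipitation and sequencing in frozen liver tumours of FVB mice that carry a doxycycline-controlled MYC transgene driven in the liver (LAP-tTA with TRE-MYC, named LAP-MYC by the labels), so that withdrawal of doxycycline switches MYC on and tumours form. Arid1a encodes a DNA-binding subunit of the SWI/SNF chromatin remodelling complex. The tumours had 3 Arid1a genotypes: floxed alleles without Cre (WT), 1 floxed allele with albumin-Cre (Het), and both alleles floxed with albumin-Cre (Homo). Each genotype had 3 MYC libraries and 3 input libraries, and the peak lists of the 9 MYC libraries were analysed. The question the design poses is whether MYC occupancy differs with Arid1a dose. The mice were about 55 days old in WT, 70 in Het and 100 in Homo, so age and Cre changed together with genotype.

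The WT lists held 92, 1567 and 4291 peaks, the Het lists 1713, 1869 and 378, and the Homo lists 112, 51 and 303, in the order of the replicate numbers. Depth per library was read from the peak values themselves: the input background ranged from 3.37 reads per kb (Homo replicate 2) to 6.27 reads per kb (WT replicate 2), and the MYC libraries from 7.80 (Het replicate 2) to 15.2 reads per kb (Het replicate 1). Of all 10376 peaks, 61.3% had their summit within 1 kb of an end of a protein-coding gene, compared with 2.91% of the sequence. The gene-end share was 15.2% in WT replicate 1 (exact 95% interval 8.58% to 24.2%) and 17.6% in Homo replicate 2 (8.40% to 30.9%), and between 43.9% and 64.4% in the other 7 libraries. Peaks away from gene ends lay more often inside genes than between them in every library, for example 24.2% and 11.4% of the peaks of WT replicate 3. The gap was small in WT replicate 1 (40 and 38 peaks). The share of sequence inside genes was not computed, so these values have no base rate beside them.

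**Figure D1:**
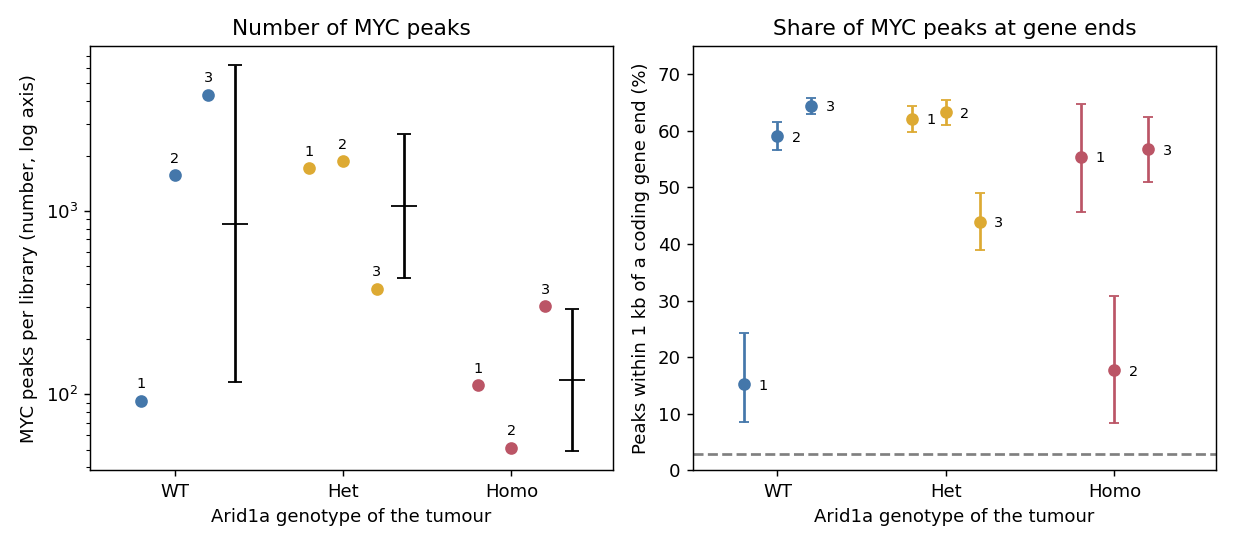
Left, number of MYC peaks per library on a log axis by Arid1a genotype, with replicate numbers beside the points and black bars for the geometric mean ± 1 SD of the log10 values (n = 3). Right, percent of each library's peaks within 1 kb of a protein-coding gene end with exact 95% binomial intervals, and a dashed line at the 2.91% of sequence that lies there; WT replicate 1 (15.2%) and Homo replicate 2 (17.6%) lie below the other libraries.

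Pooled over the 9 libraries, the genes with MYC peaks included many of ribosome production, translation and nucleotide supply. Ncl, which encodes the nucleolar protein nucleolin, carried a peak at its end in all 9 libraries, with the authors' fold over background between 8.92 and 25.5 (chromosome 1, gene span 86344719 to 86359455, summit near 86358772, mm10). Pde4a, a cyclic AMP phosphodiesterase gene, and Ube2cbp also had a peak in all 9. Srm (spermidine synthase), Xpot (a tRNA exporter), Pemt (a methyltransferase of phosphatidylcholine synthesis), Psme3 (a proteasome activator), Pdia5, and the neighbouring pairs Ccdc146 and Fam185a, Hyal3 and Ifrd2, and Vars and D17H6S56E-5, each pair sharing its peak, had one in 8 libraries. Ppia, Pcbp1, Rnf145, Rpl32, Wipf2 and Ran followed with 7.

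In the fixed gene lists, a gene was counted as bound when it had a peak at an end in at least 2 libraries, which held for 1757 of 21887 protein-coding genes (8.03%). In ribosome biogenesis 25 of 30 members were bound (odds ratio 58.1, adjusted exact p = 2.87e-22), with Ncl, Nolc1, Polr1b (an RNA polymerase I subunit) and Gnl3 in the most libraries. In ribosomal proteins 36 of 57 were bound (odds ratio 20.0, adjusted exact p = 1.79e-24), led by Rpl32, Rpl5, Rpl12 and Rpl27. In translation factors 16 of 22 were bound (odds ratio 30.8, adjusted exact p = 7.40e-13), led by Eif5a, Eef1e1, Eef1a1 and Eif1a. In nucleotide and polyamine synthesis 14 of 29 were bound (odds ratio 10.8, adjusted exact p = 4.56e-08), among them Srm, Odc1 (the rate-limiting enzyme of polyamine synthesis), Atic and Ctps. Mitochondrial biogenesis followed with 9 of 24 (odds ratio 6.90, adjusted exact p = 0.000165), including the divergent chaperonin pair Hspd1 and Hspe1, Tomm20 and C1qbp. All p-values of the gene lists are two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 17 lists, in which genes are not independent replicates. They were run over the 9 libraries together and not within a genotype. In any Homo library, 10 of 30 ribosome biogenesis, 8 of 57 ribosomal protein, 5 of 22 translation factor and 4 of 29 nucleotide and polyamine genes had a peak. The Homo libraries had a peak at the ends of only 71, 12 and 201 of the 21887 genes, in replicate order. The pooled 8.03% is thus not the base rate for these Homo counts. In the same order of lists, WT replicate 1 had 1, 0, 1 and 1 members with a peak, and Homo replicate 2 had 1, 0, 0 and 0. The background held all protein-coding genes, expressed or not, so enrichment of these lists among active genes was not tested.

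Of the circadian genes listed for their E-boxes, 9 of 14 were bound (odds ratio 20.7, adjusted exact p = 6.37e-07), with Nr1d2, Ciart, Nr1d1 and Per2 in the most libraries. The odds ratio was 10.3 without WT replicate 3 and at lowest 7.62 over the 17 settings run (highest adjusted Fisher's exact p 0.0118). MYC binds E-boxes, so this list was not chosen independently of MYC. Whether the other lists were independent of known MYC targets was not examined. The SWI/SNF list itself had 8 of 24 members bound (odds ratio 5.75, adjusted exact p = 0.000942), among them Smarca4, its ATPase, and Pbrm1, whose peak is shared with the adjoining Gnl3. Glycolysis had 5 of 20 (odds ratio 3.83, adjusted exact p = 0.0394), with Pkm and the lactate transporter gene Slc16a1, and the MYC network 4 of 14 (odds ratio 4.59, adjusted exact p = 0.0407), with Mga. The glycolysis call was lost by adjusted Fisher's exact p without WT replicate 2 (odds ratio 3.18, p = 0.102), WT replicate 3 (3.26, p = 0.196) or Het replicate 1 (3.32, p = 0.101), at odds ratios close to that of all libraries. The MYC network lost its call in the same exact test without WT replicate 3 (odds ratio 1.42, adjusted p = 0.846), Het replicate 1 (3.62, p = 0.132) or Het replicate 2 (2.36, p = 0.400), and SWI/SNF without WT replicate 3 (2.64, p = 0.262), its odds ratio being 3.73 without Het replicate 2. Over the 17 settings run, glycolysis passed in 12, the MYC network in 10 and SWI/SNF in 15, and the other 6 enriched lists passed in each. Without WT replicate 1 and Homo replicate 2, the libraries with the lowest gene-end share, 9 lists were enriched, as many as with them. These libraries had peaks at the ends of only 16 and 12 genes, so leaving them out could change little.

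No enrichment was found for cell cycle genes (5 of 30, odds ratio 2.30, adjusted exact p = 0.150), although Ccne2 and Cdt1 had peaks and the list passed in 1 of the 17 settings (within 5 kb, adjusted exact p = 0.0261), for hepatocyte identity (4 of 32, odds ratio 1.64, adjusted exact p = 0.456), for fetal liver and hepatoblastoma genes (1 of 15, Dlk1, odds ratio 0.818, adjusted exact p = 1) or for EMT and metastasis genes (1 of 22, Snai1, odds ratio 0.545, adjusted exact p = 1). Cytochrome P450 genes had 0 of 22 members bound (adjusted exact p = 0.392), their only peak being at Cyp8b1 in Homo replicate 1. The markers of other cell types were also at 0: immune cells 0 of 18 (adjusted exact p = 0.514), endothelial and stellate cells 0 of 16 (adjusted exact p = 0.770) and cholangiocytes 0 of 10 (adjusted exact p = 1). Of the loci named by the transgenes, Cebpb had a peak in 2 WT, 2 Het and 0 Homo libraries, and Alb and Myc had none at their ends in any library.

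**Figure D2:**
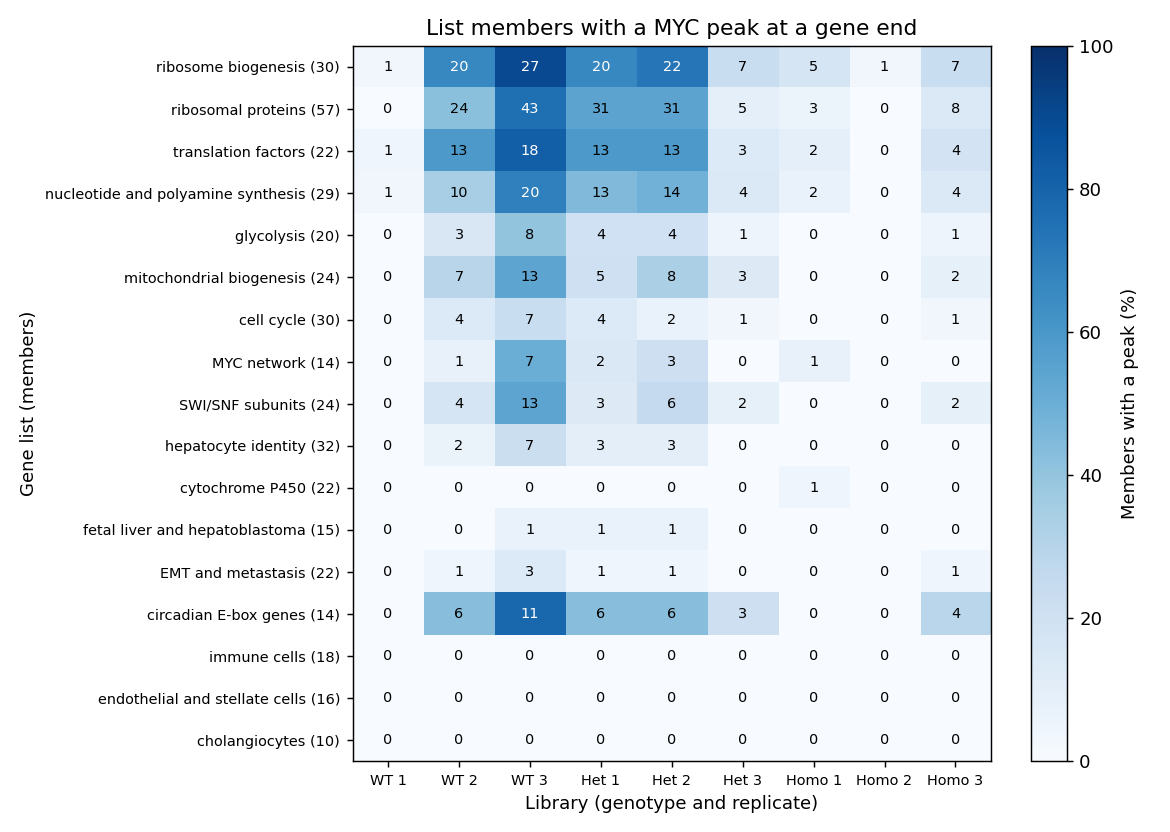
Number of members of each fixed gene list with a MYC peak within 1 kb of a gene end in each library (numbers in the cells; list sizes in brackets), shaded by percent of the list. WT replicate 3 had 27 of 30 ribosome biogenesis genes, Homo replicate 3 had 7, and the 3 lists of other cell types had 0 in every library.

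The WT and Het tumours shared most of their recurrent MYC sites. After overlapping peaks were merged into 4775 regions, 863 regions had a peak in at least 2 of 3 libraries of both genotypes, 197 had one in at least 2 WT libraries and no Het library, and 29 the other way round. Genes on the WT side included Hes1, a Notch target, Pfkl (liver phosphofructokinase), Senp5, Cdc73 (a transcription elongation factor), Dpp8, Slc6a6, the histone pair H2ac13 and H2bc13, and the neighbours Cib1 and Gdpgp1. On the Het side were Pyurf, the mitochondrial ribosomal protein genes Mrpl50 (sharing its peak with Zfp189) and Mrps18a, Gapvd1, Rasal2, Kbtbd13, Tmed3, Psmb4 and Slc20a2. All of these genes had a peak in 2 of 3 libraries of 1 genotype and in 0 of 3 of the other, and no single gene or region can pass a test with 3 libraries against 3. The number of peaks was 1983 ± 2130 (SD, n = 3) in WT and 1320 ± 819.5 in Het. The arithmetic mean was thus lower in Het, but the geometric mean was 1.25-fold higher, a log10 difference of Het from WT of 0.0971 that was smaller than the spread between libraries (two-sided exact permutation p = 0.8, adjusted p = 0.8, smallest possible p 0.1). The log10 difference turned negative without WT replicate 1 (-0.386), without Het replicate 1 (-0.00592) and without Het replicate 2 (-0.0248). The region counts depended on single libraries as well: the 197 WT regions became 2 without WT replicate 2, 0 without WT replicate 3, 341 without Het replicate 1 and 361 without Het replicate 2, and the 29 Het regions became 48, 297, 0 and 0. After thinning to the shallowest input with the same p limit in every library the direction turned, with 21 WT and 68 Het regions.

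The Homo lists lay inside those of the other genotypes. Of the peaks of the Homo libraries, between 96.4% and 100% overlapped a WT peak and between 98.0% and 99.1% a Het peak. Short lists of the other genotypes lay inside longer lists too. Of the peaks of WT replicate 1, 95.7% overlapped a Het peak, and of those of Het replicate 3, 91.0% overlapped a WT peak. The Homo overlap therefore cannot be told apart from an effect of list length. In at least 2 WT libraries and no Homo library there were 1052 regions, 697 of them at gene ends, against 0 regions in the opposite direction and 97 shared. The genes of the 1052 regions included Fbl (fibrillarin, an rRNA methyltransferase), Ppan (a nucleolar protein), Taf1c (of the RNA polymerase I selectivity factor), Usp36, Cct2 (a chaperonin subunit), G6pc3, Pds5b (a cohesin regulator), Cmc1, Ttc25 and Ankrd10, each with a peak in 2 WT libraries. Fbl had folds between 8.05 and 13.7 in its 4 libraries, all WT or Het. With each list cut to its 51 highest peaks the counts were 8 (WT not Homo) and 11 (Homo not WT), where absence means a lower rank and not a missing peak. The Homo libraries had 155 ± 131 peaks (SD, n = 3), and the geometric mean was 7.10-fold lower than in WT. This difference did not exceed the spread between libraries (log10 difference -0.851, two-sided exact permutation p = 0.3, adjusted p = 0.375), as WT replicate 1 had fewer peaks than Homo replicates 1 and 3. The log10 difference was -1.33 without WT replicate 1, -0.500 without WT replicate 3, -0.665 without Homo replicate 2 and -1.05 without Homo replicate 3. The 1052 regions became 32 without WT replicate 2 and 29 without WT replicate 3. They became 208 when the peak values of all libraries were thinned by calculation to the shallowest input and held to the same p limit. In replicate order, the input held 4.04, 6.27 and 5.62 reads per kb in WT and 3.69, 3.37 and 3.47 in Homo. Every WT input was thus deeper than every Homo input, and the 7.10-fold value is not adjusted for depth. With that thinning and p limit, the lists held 73, 445 and 1584 peaks in WT and 82, 50 and 230 in Homo. The lists of WT replicates 2 and 3 shrank the most among these libraries.

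Regions in at least 2 Het libraries and no Homo library numbered 864, of which 576 lay at gene ends, against 0 in the opposite direction and 96 shared. With each list cut to its 51 highest peaks the counts, by rank again, were 3 and 7. Mbd3 (a subunit of the NuRD complex), Ppan, Cct2, Ncoa5, Ybx3, G6pc3, Setd5, and Bap1 with its divergent neighbour Phf7 had a peak in 3 of 3 Het and 0 of 3 Homo libraries. Each Het library had more peaks than each Homo library, with geometric means 8.88-fold apart (log10 difference -0.948, two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries can give, adjusted p = 0.333). The log10 difference was -1.17 without Het replicate 3, -0.762 without Homo replicate 2 and -1.15 without Homo replicate 3. The 864 regions became 131 without Het replicate 1 and 135 without Het replicate 2, and 445 after thinning to the shallowest input with the same p limit in every library.

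**Figure D3:**
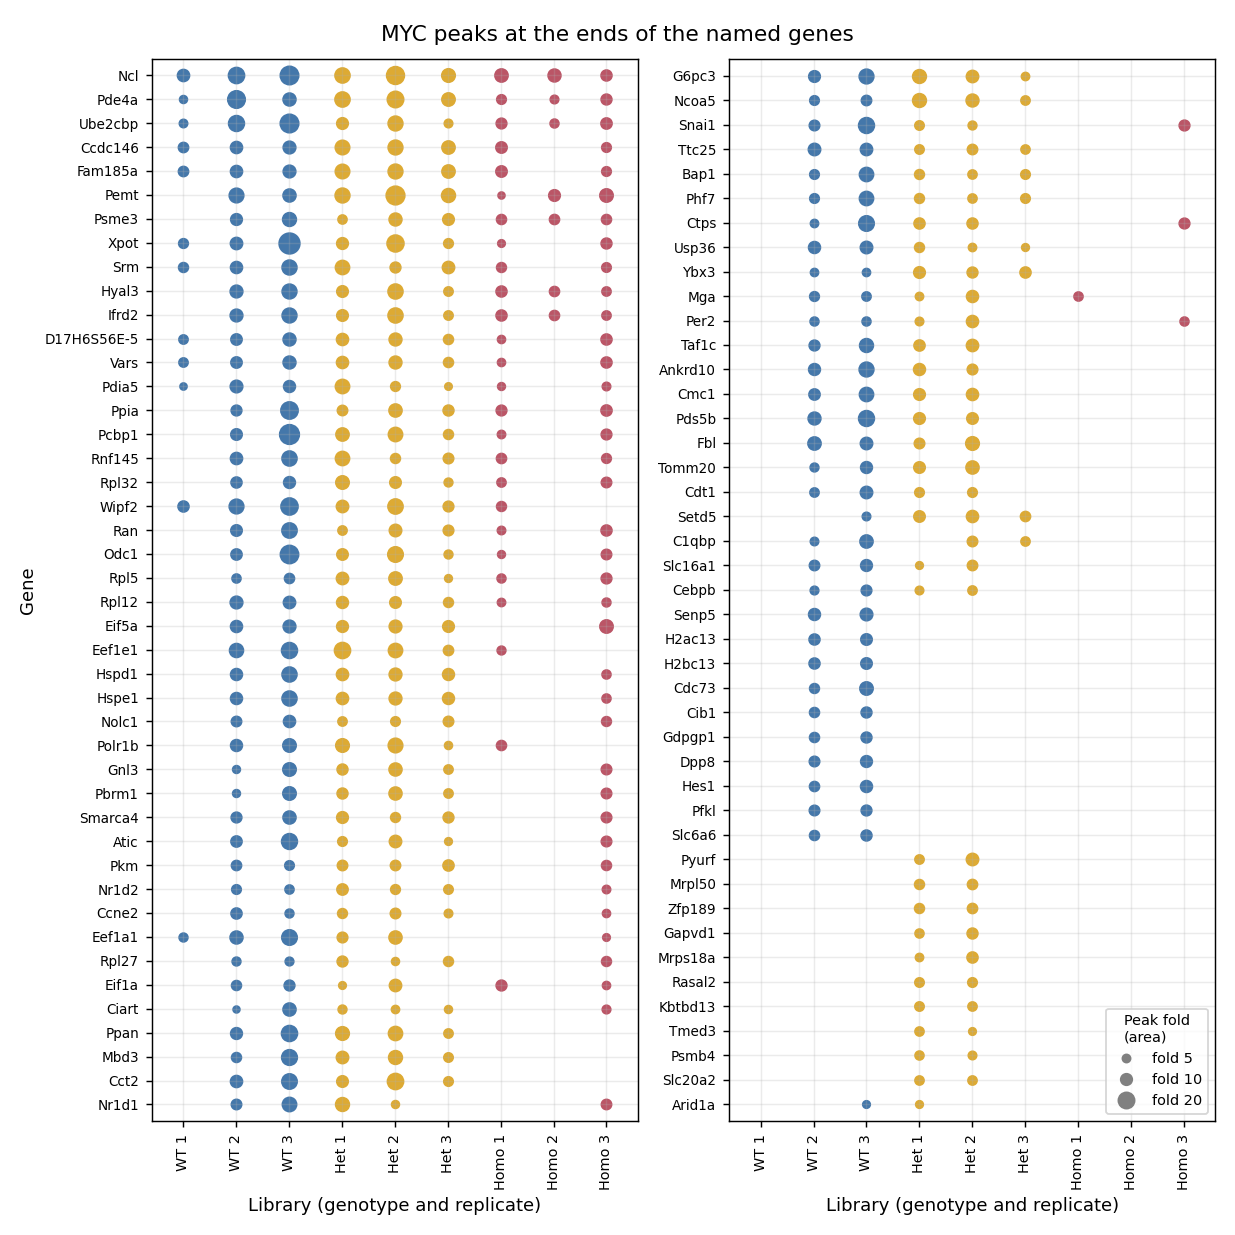
MYC peaks at the ends of the named genes in each library; a point marks a peak and its area is the authors' fold over background within that library. Ncl, Pde4a and Ube2cbp have a point in all 9 libraries, and the columns of Homo replicate 2 and WT replicate 1 hold the fewest points.

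Over the 3 genotypes together, 43.7% of the sum of squares of log10 peak number lay between genotypes (exact permutation p = 0.2, adjusted p = 0.333), and the ordered contrast of Homo against WT gave p = 0.133 by exact permutation (adjusted p = 0.333). The share was 29.1% without Homo replicate 2 and 77.8% without WT replicate 1 (exact permutation p = 0.0321, adjusted p = 0.0804). Without WT replicate 1 the ordered contrast had an exact permutation p of 0.0143 (adjusted p = 0.0714). No gene list passed the test for a difference between genotypes in its number of bound members. Ribosome biogenesis genes numbered 16 ± 13.5 in WT, 16.3 ± 8.14 in Het and 4.33 ± 3.06 in Homo (SD, n = 3, exact permutation p = 0.293, adjusted p = 0.691), and ribosomal protein genes 22.3 ± 21.5, 22.3 ± 15.0 and 3.67 ± 4.04 (exact permutation p = 0.307, adjusted p = 0.691). By the same permutation test, 0 of 17 lists passed, and 0 had an unadjusted value under 0.05, the lowest being 0.239 for mitochondrial biogenesis. Without WT replicate 1 the lowest permutation p over the lists was 0.0214 (adjusted p = 0.182). Genes with a peak at an end numbered from 12 in Homo replicate 2 to 3090 in WT replicate 3. Of these genes, ribosome biogenesis made up 1 of 16, 20 of 1063 and 27 of 3090 in WT, in replicate order. It made up 20 of 1221, 22 of 1343 and 7 of 187 in Het, and 5 of 71, 1 of 12 and 7 of 201 in Homo. The lower member counts in Homo therefore do not show a loss particular to these lists. Arid1a itself had a weak peak at its end in 1 WT and 1 Het library (folds 4.19 and 4.25) and in 0 Homo libraries.

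The gene-end share did not separate the genotypes, at 46.2% ± 27.0 in WT, 56.4% ± 10.9 in Het and 43.3% ± 22.2 in Homo (SD, n = 3, exact permutation p between 0.5 and 0.877 over the 5 tests, adjusted p = 0.877). The mean share of the shorter list found in the longer one was 79.3% within and 84.1% between genotypes (difference -4.80, one-sided exact permutation p = 0.811). The sign turned without Homo replicate 2 (1.67) and with the Jaccard index (3.01, one-sided exact permutation p = 0.221). The share of the shorter list depends on list length, which differed between genotypes. Pairs of Homo lists shared 47.1%, 67.9% and 82.4%, whereas the Homo lists shared 96.4% to 100% with WT replicate 3. The difference therefore does not show whether libraries of 1 genotype are more or less alike. Single pairs ranged from 28.3% to 100%, compared with at most 2.17% for randomly placed peaks. The random placement was uniform along each chromosome and ignored the excess of peaks at gene ends. It therefore does not show sharing beyond that excess.

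Regions found in all 9 libraries numbered 16, and 3 of them lay at a protein-coding gene end. Such regions must be in WT replicate 1 and Homo replicate 2, which had 14 and 9 peaks at gene ends. The gene-end share was 58.8% for regions in 1 library, 71.9% in 4, 54.6% in 6, 48.8% in 7 and 30% in 8. Of the other 13, the 5 with the highest mean rank over the 9 libraries lay at chromosome 5, 142367301 to 142367920 (fold 10.3 to 22.0, outside coding genes, 474 bp from an end of the lncRNA gene Gm31068), chromosome 14, 79305063 to 79305454 (fold 7.69 to 34.0, 3619 bp from Rgcc), chromosome 15, 79978459 to 79979222 (fold 10.8 to 37.9, 7746 bp from Cbx7), chromosome 11, 6710235 to 6711073 (fold 9.42 to 33.2, outside coding genes), and chromosome 15, 36908659 to 36909276 (fold 6.74 to 34.2, outside coding genes). Sequence motifs at the summits were not analysed here.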

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

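The alternatives that left out WT replicate 1 and Homo replicate 2 together, used the same p limit in every library, thinned to the shallowest input, or used gene ends of any biotype were chosen after seeing the data. Of the values that answer a comparison, 287 kept their direction and their side of the threshold or stayed within 1.5 times, 20 reversed and 31 moved further; of the odds ratios of single lists 253 kept theirs, 14 lost a call, 1 gained one and 4 reversed. No genotype test of peak number or gene-end share passed under any setting run (lowest adjusted exact permutation p 0.0714). The log10 peak difference of Het from WT was -0.386 without the 2 libraries left out together and -663 peaks when not logged, and the gene-end share difference was -5.28 without those 2 libraries. Within 5 kb of gene ends, Homo differed from WT in gene-end share by 0.406, in the pair and in the ordered contrast, and the odds ratio of fetal liver genes was 1.24. Among the 51 highest peaks of each list, the share difference was 15.7 for Homo against WT, pair and ordered contrast, and 1.96 for Homo against Het, and regions numbered 5 (WT not Het), 4 (Het not WT), 8 (WT not Homo), 11 (Homo not WT), 3 (Het not Homo) and 7 (Homo not Het), where absence means a lower rank and not a missing peak. The Jaccard index put overlap within genotypes 3.01 higher than between (one-sided exact permutation p = 0.221). Bound in 4 or more libraries, EMT genes had an odds ratio of 1.52. A fold of at least 5 gave 57 regions in Het not WT and 1 in Homo not WT. Requiring 3 of 3 libraries gave 0 (WT not Het), 0 (Het not WT), 29 (WT not Homo) and 119 (Het not Homo), by construction fewer. Thinned to the shallowest input, regions numbered 21 (WT not Het), 68 (Het not WT), 208 (WT not Homo), 1 (Homo not WT), 445 (Het not Homo) and 1 (Homo not Het), against 811 (WT not Homo) and 642 (Het not Homo) with the same p limit alone. These counts thus depend on depth, in part by construction, as the calculation lowers peak values most where the input is deepest. Without WT replicate 1 and Homo replicate 2 they were 195 (WT not Het), 29 (Het not WT), 1056 (WT not Homo) and 870 (Het not Homo). Leaving out each library gave -0.386 to 0.448 for log10 peaks of Het against WT, -1.33 to -0.500 for Homo against WT, -1.17 to -0.762 for Homo against Het, 29.1 to 77.8 for the percent between genotypes, -5.28 to 19.3 for the gene-end share of Het against WT, -18.5 to 9.84 for Homo against WT in the pair and the ordered contrast, -13.7 to 1.67 for overlap, 0.818 to 1.32 for the fetal liver odds ratio, 1.42 to 5.08 for the MYC network, 2.64 to 5.77 for SWI/SNF, 10.3 to 20.8 for circadian E-box genes, and region counts of 0 to 361 (WT not Het), 0 to 297 (Het not WT), 29 to 1242 (WT not Homo), 131 to 1049 (Het not Homo) and 0 to 1 (Homo not Het). For the gene-end share, leaving out each library also gave -19.9 to -0.380 for Homo against Het and 4.26 to 27.7 for the percent between genotypes. Apart from the constructions named, the cause was not tested.

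Replicate numbers did not pair the libraries: deviations from the genotype means correlated between -0.239 and 0.185 for the same number (median -0.0330) and between -0.313 and 0.279 for other numbers, WT replicate 1 deviating most like Het replicate 3. With the replicate block the log10 peak difference of Homo from Het stayed -0.948, with an exact permutation p of 0.25, the smallest that a block of 3 pairs can give, and the block changed no call. The motif counts and the CpG-rich background were not run.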

Other observations

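Several of the recurrent MYC sites outside protein-coding gene ends lay at non-coding RNA genes; they were picked after their values were seen. A peak 49 bp from an end of Pvt1, the non-coding neighbour of Myc, was present in 8 libraries (chromosome 15, 62037759 to 62038262, fold 6.14 to 16.2), 47674 bp from Myc, although Myc itself had no peak at its ends. Snhg15, a small nucleolar RNA host gene, had a peak 78 bp from its end in all 9 libraries (fold 5.07 to 26.4), and Snhg17 one 75 bp from its end in 8 (fold 4.88 to 19.7). A pair of regions lay 1299 and 3044 bp from Mir17, of the miR-17 cluster, in 7 libraries each (fold 6.77 to 27.9 and 5.004 to 13.0). Npm1, a nucleolar chaperone gene, had a peak 1754 bp from its end in 8 libraries.

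On chromosome 7, regions 1282 bp from Gm8728 (8 libraries), 1293 bp from Gm8486, 1295 bp from Gm16443 and 1284 bp from Gm8685 (7 libraries each) lay near pseudogenes among the Vmn1r receptor genes, and a region of 8 libraries there lay 8996 bp from Gm4541. The distances of 1282 to 1295 bp from different pseudogenes were nearly equal. A region at chromosome 1, 24612507 to 24614147, had peaks in 7 libraries with folds of only 1.62 to 2.13. No filter for repeated sequence was applied here. Whether reads at the regions on these chromosomes map to more than 1 place was not tested.

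Of the tests that follow, those of input depth, of the strongest peaks, of the transgene loci, of the correlation within genotypes, of enrichment by genotype and of other splits of the libraries were chosen after the results they measure were seen.

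The longest list had 84.1 times as many peaks as the shortest, and lists of 1 genotype differed widely too (92 to 4291 in WT, 378 to 1869 in Het and 51 to 303 in Homo). Input depth as the whole cause is argued against by the ratio of 31.7 that remained after all libraries were thinned to the shallowest input and held to 1 p limit (65.8 with that limit alone). This ratio sets WT replicate 3 against Homo replicate 2. The thinned lists held 73 to 1584 peaks within WT, 242 to 1348 within Het and 50 to 230 within Homo. The argument thus extends to the WT lists, while the narrower ranges within Het and Homo do not decide it. Weaker enrichment over background may be a candidate explanation: the median enrichment at the 16 regions found in all libraries rose with log10 peak number (Pearson r = 0.901, exact permutation p = 0.00287; Spearman rho = 0.817, p = 0.0108; without the 2 farthest libraries r = 0.885, p = 0.0109, and rho = 0.714, p = 0.0881; within genotypes r = 0.852, exact permutation p = 0.0139; no other measure was correlated). That enrichment was 63.5 ± 8.52 in WT, 66.3 ± 11.3 in Het and 41.9 ± 4.10 in Homo (SD, n = 3, exact permutation p = 0.0286 over 3 genotypes, adjusted p = 0.125 over 5 tests), so whether it reflects the yield of the precipitation, genotype or age stays open. The same summit reads enter the peak calls, which ties both measures together.

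WT replicate 1 and Homo replicate 2 had few peaks at gene ends and the shortest fragments (170 and 173 bp). If short lists hold only the strongest peaks, the 51 highest peaks of the other lists could be as poor in gene ends; 5 of the other 7 libraries lay above the upper limit of Homo replicate 2 (30.9%), while WT replicate 2 was at 9.80%, so this stays undecided. Lower enrichment at gene ends than elsewhere in these libraries is open too: their ranks from the lowest ratio of 9 summed to 5 (1 and 4), where the lowest pair gives 3. The ratio used only regions with a peak in all 9 libraries, 3 at gene ends and 13 elsewhere. Gene ends without a peak in these libraries were thus left out, so the ratio cannot decide the question. No biological explanation was tested, and the libraries belong to different genotypes.

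The 13 regions away from gene ends that all 9 libraries shared could lie where the input itself is high. Their local background was 2.36 times the genome background at the median (range 1.22 to 5.15), next to 2.14 for all peaks, which decides neither way. Loci named in the transgenes are argued against, as 0 of the 13 lay within 100 kb of Alb, Cebpb or Myc. Binding of the antibody to another protein and sites of MYC itself were not tested, as no control antibody or sequence was used here.

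The splits of 6 libraries into 3 against 3, the real one included, number 10, too few to give a share under 0.05. As many regions found on 1 side only as between WT and Het (226) came from 9 of the 10 splits (highest other 882), as many as between WT and Homo (1052) from 2 (highest other 1220), and as many as between Het and Homo (864) from 1, the real one (highest other 837). For the gene lists, 100 of 100 partitions of the 9 libraries gave as many lists past the threshold as the real 0 (highest other 0), which a count of 0 makes certain and which therefore says nothing about chance.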
